A study of Mus musculus with 8 samples.

How the data were processed

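mRNA of J1 mouse ES cells was profiled in 8 libraries, 2 in each of KD control, KD Zscan4, OE control and OE Zscan4. Per the labels, cells received 1000 ng of plasmid, selection began after 24 h, and single clones were picked. Puromycin (2 µg/ml) was given for 7 days in the knockdown arm and G418 (500 µg/ml) for 10 days in the overexpression arm. Medium held 15% serum and 10 ng/ml LIF, and libraries were amplified for 11 PCR cycles, without molecular identifiers stated in the labels.

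Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to mm10 with HISAT2, counted with featureCounts and normalised with DESeq2. No versions were stated. The authors deposited 4 tables of signal values, a gene table and a repeat name table for each arm. Tested on the files, the deposited gene values are whole reads divided by one factor per library: multiplied back, 100% of values lay within 0.01 of a whole number. These factors equal DESeq2's median-of-ratios factors computed on the same table. Repeat values met the same criterion in 100% of cases, and the reads recovered in this way were used for the other scalings of repeats. No claim of whole reads was made for repeats, and no count test was run there. Factors read from the steps between repeat values lay close to median-of-ratios factors over genes and repeats together, with ratios of 0.99926 to 1.00065. Whether counting used strand is not stated, so antisense and overlapping genes are uncertain, as are near-identical copies such as those of Zscan4.

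Samples were grouped by their titles. The tests, lists, naming rule and most alternatives were chosen before the data were examined. The plan named edgeR for read counts and limma-trend for normalised values. Since the tables hold normalised signal, limma-trend on log2(value + 1) took the place of edgeR, with 2 against 2 libraries, two-sided tests, Benjamini-Hochberg adjustment over all genes or repeats of a table and a false discovery rate of 0.05. A table's genes were all tested, because low values had already been left out of the deposited tables. The share of genes whose libraries were separated by group was 67.8% in the knockdown and 71.2% in the overexpression, where chance gives 33.3%. The Zscan4 family sum was fitted as an extra entry and has an unadjusted p.

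The difference between the effects was tested in the 17409 genes of both tables as a contrast of within-arm differences. The difference between controls used recovered reads of these genes, scaled jointly with TMM. Overlaps of calls were tested with Fisher's exact test.

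Gene lists (21) and repeat lists (7) were tested with camera on the same log2 values, with a preset correlation of 0.01 between genes and with an estimated correlation, adjusted over the lists. They covered the Zscan4 family, 2-cell-like genes, naive and formative pluripotency, primitive endoderm, trophectoderm, mesoderm, neural ectoderm, fibroblasts, germline genes, repressors, telomeres and meiotic recombination, p53 targets, the integrated stress response, interferon response, imprinting, glycolysis, cholesterol synthesis, mitochondrial genes, histones and Y-linked genes. Repeat lists covered MERVL, IAP, ETn with MusD and MERVK, ERV1, young LINE-1, MaLR and SINE elements, and a list of satellites had no measured member.

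Genes named by rule were the Zscan4 family, the 10 largest rises and 10 largest falls that passed with a mean of at least 1 CPM and separated groups, and up to 4 passing members per list with the largest changes. Of genes called in both comparisons, the 5 opposite and 5 same-direction genes with the largest smaller change were taken. Dux, Zfp352, Tcstv1, Tcstv3, Usp17lc, Gm4340, Pou5f1, Nanog, Trim28, Cdkn1a, MERVL-int and MT2_Mm were named whatever their result, and of repeats the 5 largest rises and falls. Other members, named where a count was small or did not pass, genes of chromosome Y outside the list, and Gata6 in the closing section, were chosen after their values were seen. Some list members are counted in their list but not reported here by name. Where a group had 1 to 3 reads, the ratio is given with a 95% interval that covers counting error alone.

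The procedure was tested on simulated data with 200 changed genes and 20 changed repeats. Of 100 genes changed 2-fold, 72 were recovered in the knockdown and 73 in the overexpression, and of 100 changed 4-fold, 95 and 87. Unchanged genes were 5.11% and 0.62% of calls. For repeats, 4 and 6 of 10 changed 2-fold and 9 and 10 of 10 changed 4-fold were recovered, and unchanged repeats were 13.3% and 15.8% of calls. Camera found the changed list in each simulation with the preset correlation and missed it with the estimated one. Genes were drawn independently of each other there, so the preset correlation itself was not tested. All entries of a table were drawn with a common dispersion, and far fewer genes were changed than were called in the data. These rates of recovery and of false calls may therefore not hold for the data.

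Alternatives were DESeq2, limma-voom and edgeR on recovered reads, other scalings and thresholds, a pseudocount of 0.1, all 8 libraries in one fit, a replicate block, each library left out, other set tests, a mean of at least 20, and chromosomes 1, 11 and Y left out. Symbols were matched for 17913 of 17938 and 18259 of 18292 identifiers against GENCODE. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.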

Results

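RNA was sequenced from J1 mouse embryonic stem (ES) cells, a line derived from a male embryo, in 8 libraries that formed 4 groups of 2. In the knockdown arm, cells carried a pSuper-puro vector with a short hairpin RNA (shRNA) against Zscan4 (KD Zscan4) or a random control (KD control). In the overexpression arm, cells carried the Zscan4c coding sequence in pCMV-tag2 (OE Zscan4) or its control (OE control). Each arm had a gene table and a table of repeats summed by repeat name, both of normalised values. The gene tables corresponded to 21.76 and 17.39 M reads in KD control, 19.57 and 19.98 M in KD Zscan4, 20.32 and 17.98 M in OE control, and 19.49 and 22.38 M in OE Zscan4. The tables covered 17938 genes and 767 repeat names in the knockdown arm, and 18292 genes and 834 repeat names in the overexpression arm.

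Levels are means ± SD over the 2 libraries of a group in these normalised values. Fold changes are on the log2(value + 1) scale, Zscan4 group minus its own control, which understates the change of low genes. Adjusted p-values come from limma, and those of gene lists from camera in limma. Within each group the libraries differed by more than counting noise, with a chi-square per degree of freedom of 2.94 to 4.96 over genes, so each counted as a library of its own. The labels do not say whether replicates were separate clones or cultures, so the p-values measure only the spread between these samples, which may be technical. Coordinates refer to mm10.

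The knockdown comparison asked which transcripts moved when Zscan4 was targeted. Zscan4 is a cluster of near-identical zinc finger genes on chromosome 7, from 10794242 to 11614112, active in the 2-cell embryo and in a minority of cultured ES cells. The summed signal of the 9 measured members was 3544 ± 294 in KD control and 117 ± 27.2 in KD Zscan4 (n = 2 each), a log2 fold change of -4.93 (SE 0.13). Its unadjusted limma p was 5.8e-14. Zscan4c (ENSMUSG00000054272, chromosome 7, 11005745 to 11010547) fell from 570 ± 6.31 to 13.3 ± 3.09, with a log2 fold change of -5.33 (SE 0.19, limma adjusted p = 3.1e-09). All 9 members fell, also when adjusted over the list alone, with a median log2 fold change of -5.25 (limma camera adjusted p = 1.8e-13). The camera call was lost with an estimated correlation (limma adjusted p = 0.195 with an estimated correlation). Reads can be shared between these copies, so the values of single members are less certain than their sum.

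**Figure D1:**
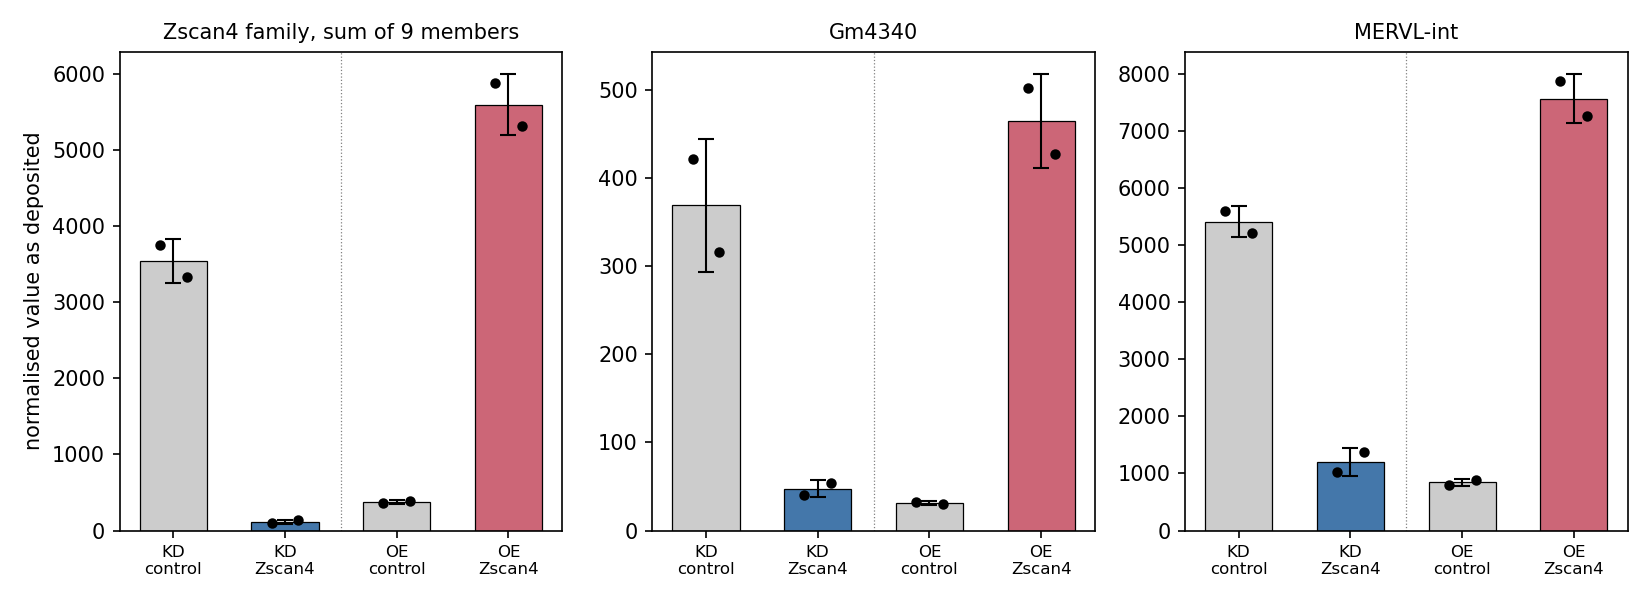
Normalised values as deposited of the Zscan4 family sum, Gm4340 and MERVL-int in the 4 groups, with bars at the mean, error bars of 1 SD and points for the 2 libraries. The family sum was 3544 in KD control, 117 in KD Zscan4, 375 in OE control and 5595 in OE Zscan4, and the knockdown and overexpression tables were normalised separately.

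Genes known from the 2-cell embryo and from 2-cell-like ES cells fell with Zscan4. Of 36 measured members of that list, 31 fell and none rose, and 33 fell when adjusted over the list alone. The median log2 fold change was -2.44 (camera adjusted p = 7.0e-15, adjusted p = 0.195 with an estimated correlation). Gm4340, a member of this list, fell from 369 ± 75.1 to 47.5 ± 9.73 (log2 fold change -2.93, SE 0.18, limma adjusted p = 3.2e-07). Gm21304 fell from 162 ± 39.0 to 17.3 ± 1.56, Usp17lc, a deubiquitinase gene, from 73.4 ± 20.1 to 7.94 ± 0.25, and Tcstv3 from 30.3 ± 4.83 to 2.47 ± 0.62. Duxf3 (Dux), a transcription factor gene that activates the 2-cell program, had 27 reads in KD control and 1 in KD Zscan4, a ratio of 0.0369 (95% counting interval 0.00090 to 0.224). Zfp352 had 22 reads against 1, a ratio of 0.0453 (0.0011 to 0.280). Its call was lost without KD control replicate 1, where its log2 fold change was -2.66. The 5 members that did not pass were Pramef25 (-0.94), Trim43a (-0.72), Trim43b (-0.34), Gm2035 (-1.12) and Gm2056 (-1.28). Tcstv1 was not analysed here.

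Across all genes, 6401 of 17938 passed at a false discovery rate of 0.05, of which 3081 rose and 3320 fell. At least 2-fold changes were called for 686 rises and 701 falls. DESeq2 on the recovered reads called 4137, all of them among the 6401.

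The largest rises were in noncoding RNAs of the imprinted Dlk1-Dio3 region on chromosome 12 and in X-linked genes. Meg3 (109541001 to 109571726), a maternally expressed long noncoding RNA, had 2 reads in KD control and 1398 in KD Zscan4, a ratio of 696 (95% counting interval 192 to 5753). Rian (109603940 to 109661716) rose from 4.37 ± 1.42 to 1747 ± 30.0 (log2 fold change 8.37, SE 0.19, limma adjusted p = 1.5e-10), and Mirg (109729764 to 109749460) had 2 reads against 188, a ratio of 93.6 (25.6 to 779). Of the X-linked genes, Xlr3a rose from 2.02 ± 0.32 to 128 ± 2.99 (5.42), the homeobox genes Rhox10 from 11.3 ± 1.72 to 163 ± 10.7 (3.74) and Rhox13 from 16.6 ± 10.7 to 171 ± 17.1 (3.44). Other large rises were Gm16063 (3.43), the cytokine gene Il17f (3.17), Platr6 (3.12) and the calcium pump gene Atp2b4 (2.90). The Platr6 call was lost with DESeq2, where its log2 fold change was 2.72. Il17f and Atp2b4 lie on chromosome 1. Beside Zscan4 members, the largest falls were Ddx3y on chromosome Y, from 408 ± 22.4 to 6.38 ± 4.71 (-5.96), and Cubn, which encodes an endocytic receptor of visceral endoderm, from 635 ± 11.0 to 11.5 ± 8.08 (-5.83, SE 0.34, limma adjusted p = 1.8e-07). Srgn (-5.15) and Foxq1 (-4.75) followed.

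Genes of extraembryonic endoderm fell as a group. Of 24 primitive endoderm genes, 20 fell, the same number as adjusted over the list alone, with a median of -2.12 (camera adjusted p = 2.5e-17, adjusted p = 0.195 with an estimated correlation). Sox17, a transcription factor gene of endoderm, fell from 178 ± 20.2 to 7.48 ± 2.34. Nid1, Hnf4a, Apoa1 and Cited1 did not pass, with values between -0.34 and -0.02. Among formative and primed pluripotency genes, 15 of 20 fell and 1, Otx2 (0.60), rose, with the same counts adjusted over the list alone. Their median was -0.53 (camera adjusted p = 1.4e-07, adjusted p = 0.256 with an estimated correlation), with Sox3 at -2.19, Lef1 at -1.41, Lefty1 at -1.39 and the DNA methyltransferase gene Dnmt3b at -1.36. Naive pluripotency genes went both ways, 15 of 30 falling and 7 rising (16 and 7 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.021, adjusted p = 0.290 with an estimated correlation). In this list Lin28a fell from 7216 ± 238 to 3464 ± 30.7 (-1.06), Klf5 (-0.83) and Nr0b1 (-0.82) fell, and Nr5a2 rose (0.75). Nanog rose from 10664 ± 31.8 to 13605 ± 383 (0.35, limma adjusted p = 1.4e-04). Pou5f1, which encodes Oct4, did not pass (-0.13, limma adjusted p = 0.078), but did with limma-voom (-0.13) and without KD Zscan4 replicate 1 (-0.19). It passed without KD Zscan4 replicate 1 at -0.19 and with limma-voom.

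Mesoderm and primitive streak genes fell in 9 of 20 cases, with 9 adjusted over the list alone, none rose, and the median was -1.04 (camera adjusted p = 3.8e-05, adjusted p = 0.195 with an estimated correlation). Meis1 (-2.69), Snai1 (-1.64) and Id1 (-1.54) were among them. Wnt3 (-3.35) was called by limma and not by DESeq2 (-2.73). Of 14 neural ectoderm genes, 10 fell and Tubb3 (0.71), Map2 (0.55) and Stmn2 (0.16) rose, with the same counts adjusted over the list alone and a median of -0.62 (camera adjusted p = 0.0038, adjusted p = 0.195 with an estimated correlation). Gbx2 fell from 3694 ± 80.7 to 1139 ± 39.3 (-1.70) and Sox11 was at -1.47. In the trophectoderm list Esx1 (2.12), Rhox6 (0.91) and Tfap2c (0.76) rose and Peg10 (-1.91), Cdx2 (-1.13), Gata2 (-1.07), Krt8 (-0.69) and Eomes (-0.67) fell among 18, with the same 3 and 5 adjusted over the list alone. Its median was 0.0071, its mean -0.07 and the test pointed down without passing (limma camera adjusted p = 0.658). In the fibroblast and mesenchyme list 5 of 22 rose, among them Thy1 (0.91), Fn1 (0.79), Col6a2 (0.75) and Col5a1 (0.70), and Twist1 (-2.85) and Vim (-0.65) fell, the same counts as adjusted over the list alone. The median was 0.09, the mean -0.0071 and the test pointed up without passing (limma camera adjusted p = 0.447).

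Germline genes rose in 13 of 27 cases and Rpl10l (-0.47) fell, with the same counts adjusted over the list alone and a median of 0.34 (camera adjusted p = 3.9e-04, adjusted p = 0.195 with an estimated correlation). Stra8, a gene of meiotic entry, rose from 511 ± 7.51 to 2259 ± 99.1 (2.14, SE 0.06, limma adjusted p = 6.9e-10), and Xlr3b had 3 reads against 35, a ratio of 11.6 (3.66 to 59.0). Telomere and meiotic recombination genes rose in 12 of 27 cases, while Dkc1 (-0.35) and Rtel1 (-0.30) fell (13 and 3 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.020, adjusted p = 0.492 with an estimated correlation), and the cohesin gene Smc1b rose from 12.8 ± 2.19 to 52.6 ± 0.25 (1.97). That call was lost without KD Zscan4 replicate 2 (limma adjusted p = 0.0817) and with fry (0.101), in a range over its alternatives from 0.0020 to 0.492. Repressors of retroelements and heterochromatin fell in 21 of 41 cases and Atrx (0.46) and Chaf1b (0.19) rose (22 and 2 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 5.1e-05, adjusted p = 0.251 with an estimated correlation). Myc, which was on this list, fell from 2241 ± 40.8 to 683 ± 34.8 (-1.71, SE 0.06, limma adjusted p = 4.6e-09), with Mycn at -0.76, Dppa2 at -0.73 and Dnmt3l at -0.71. Trim28, the corepressor of KRAB zinc finger proteins, was at -0.21 (limma adjusted p = 0.0076) and did not pass without KD control replicate 1 (-0.23) or replicate 2 (-0.19).

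Targets of p53 fell in 14 of 26 cases, with Gdf15 (0.69) and Sesn1 (0.55) rising (15 and 2 adjusted over the list alone). The median was -0.30 (camera adjusted p = 5.1e-06, adjusted p = 0.301 with an estimated correlation), and Plk2 fell from 1223 ± 86.4 to 389 ± 59.2 (-1.65), with Perp at -1.22 and Pmaip1 at -0.97. Cdkn1a did not pass (-0.20, limma adjusted p = 0.077) but did without KD Zscan4 replicate 1 (-0.28). Integrated stress response genes rose in 13 of 26 cases, and Ddit4 (-0.37), Slc3a2, Slc7a5 and Ppp1r15a (-0.19 each) fell (14 and 6 adjusted over the list alone). Their median was 0.23 (camera adjusted p = 0.0026, adjusted p = 0.195 with an estimated correlation), with the asparagine synthetase gene Asns at 1.05 and Psat1 at 1.01. Of 22 interferon response genes, 7 rose and Tap1 (-1.44), Ifitm3 (-1.15), Ddx58 (-0.38) and Bst2 (-0.36) fell (9 and 4 adjusted over the list alone). The median was 0.31 and camera did not pass (limma adjusted p = 0.151), although Oas1a rose from 34.2 ± 2.30 to 193 ± 0.25 (2.46).

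Genes of sterol synthesis and glycolysis rose. Of 24 cholesterol synthesis genes, 19 rose and Ebp (-0.34) fell (19 and 2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 9.3e-09, adjusted p = 0.195 with an estimated correlation). Hsd17b7 was at 1.103, Fdft1 rose from 1183 ± 141 to 2395 ± 126 (1.02), and Srebf2 and Tm7sf2 were among those that did not pass. Glycolysis and hypoxia genes rose in 16 of 32 cases and Slc2a1 (-0.69), Ndrg1 (-0.53), Egln3 (-0.27) and Pdk1 (-0.26) fell (18 and 5 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0021, adjusted p = 0.515 with an estimated correlation), with Pfkp at 1.06 and Ankrd37 at 0.96. This call was lost with fry (limma adjusted p = 0.0929, and 7.9e-06 to 0.515 over its alternatives). Of 13 mitochondrially encoded genes, 6 rose and none fell, the same adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0073, adjusted p = 0.515 with an estimated correlation). That call was lost without KD control replicate 2 (limma adjusted p = 0.108) or KD Zscan4 replicate 2 (0.0589) and with fry (0.234), and the range over its alternatives was 5.1e-08 to 0.515. Among 48 replication-dependent histone genes, 9 fell and none rose (5 and none adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.021, adjusted p = 0.517 with an estimated correlation). It was lost without KD control replicate 1 (limma adjusted p = 0.161), without KD Zscan4 replicate 2 (0.200), with fry (0.144) and without chromosomes 1, 11 and Y (0.0518), in a range over its alternatives from 0.0041 to 0.517.

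Of 36 imprinted genes, 13 fell and Meg3, Rian, Mirg and Usp29 (1.48) rose, the same counts as adjusted over the list alone. The median was -0.14 and the test pointed down (camera adjusted p = 0.016, adjusted p = 0.251 with an estimated correlation), while the mean was 0.28. Without chromosomes 1, 11 and Y the call was lost (limma adjusted p = 0.0764, and 0.0031 to 0.251 over its alternatives). Cdkn1c, which encodes a cell cycle inhibitor, fell from 695 ± 52.96 to 96.9 ± 22.2 (-2.85, SE 0.14, limma adjusted p = 5.7e-08).

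Genes of chromosome 1 were higher in KD Zscan4 along its whole length. The median log2 fold change of its 703 protein-coding genes with a mean of at least 20 was 0.56 (quartiles 0.35 and 0.75), a fold of 1.47, and 91.0% were positive. The medians of the other 18 autosomes lay between -0.07 and 0.02. Chromosome 1 held 654 of the 6401 called genes, of which 616 rose and 38 fell. Rises given for single genes of this chromosome, list members among them, were not adjusted for its shift. Without chromosomes 1, 11 and Y, a choice made after this shift was seen, 5139 genes were called.

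All 4 measured members of the Y-linked list fell, the same number as adjusted over the list alone, with a median of -2.32 (camera adjusted p = 3.7e-04, adjusted p = 0.195 with an estimated correlation). KD Zscan4 retained 1.56% of the KD control level of Ddx3y, 18.1% of Uty, 19.6% of Uba1y and 77.5% of Eif2s3y. Eif2s3y was at -0.37 (640 ± 56.6 against 496 ± 62.3), and its call was lost without KD control replicate 1 (-0.28), without KD Zscan4 replicate 1 (-0.24) and in the fit of all 8 libraries. Of 9 genes annotated to chromosome Y, 5 fell, with Gm2098 at -1.44 beside these 4, and the processed pseudogene Gapdh-ps15 rose (0.21). Gm20775, Gm47283 and Gm29650 did not pass.

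**Figure D2:**
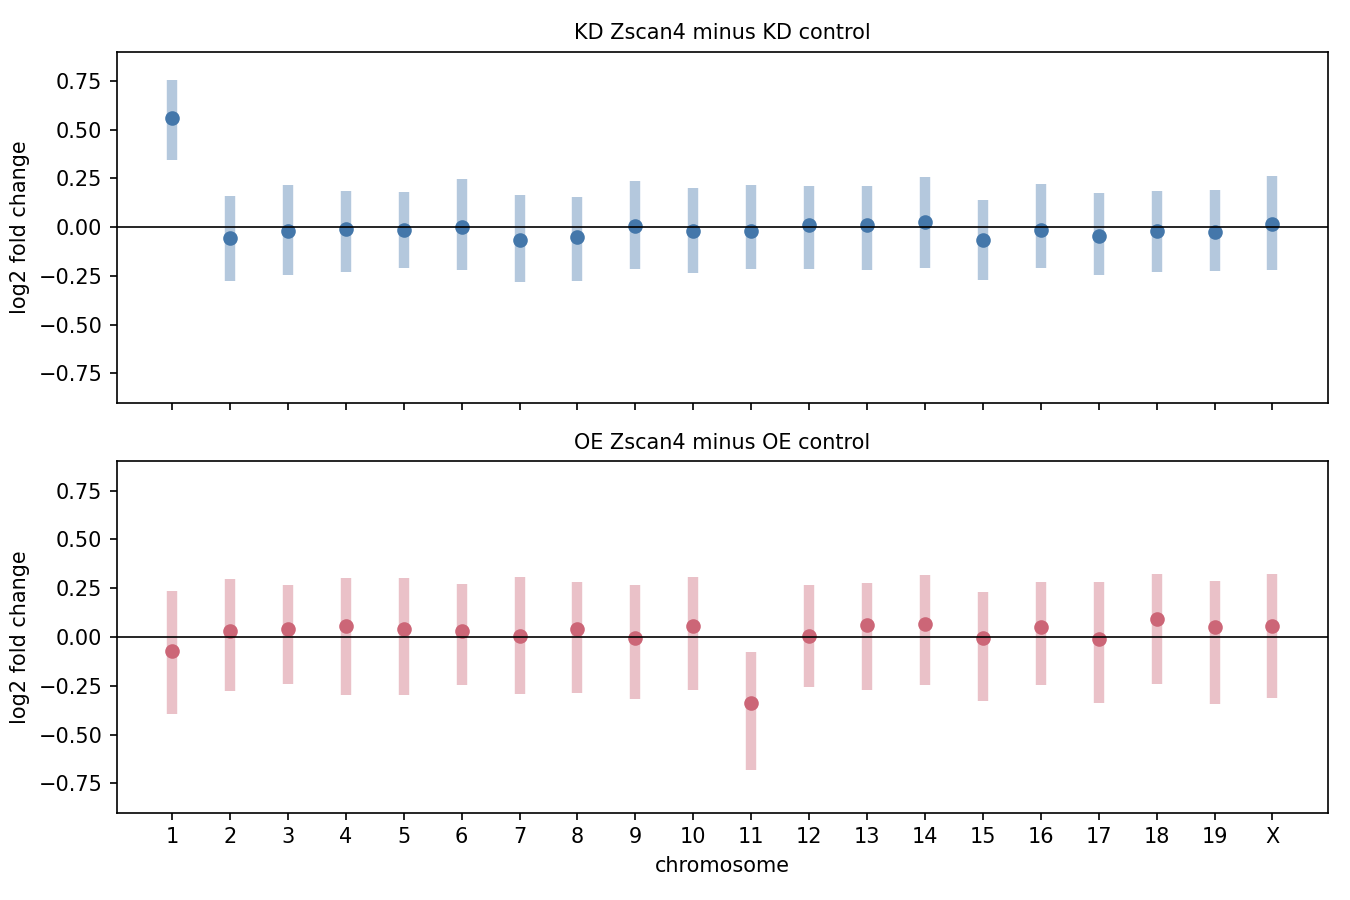
Median (points) and quartiles (bars) of the log2 fold change of protein-coding genes with a mean of at least 20, by chromosome, for KD Zscan4 minus KD control and OE Zscan4 minus OE control. Chromosome 1 stood at 0.56 in the knockdown and chromosome 11 at -0.34 in the overexpression.

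Among repeats, MERVL, the endogenous retrovirus of the 2-cell stage, fell. MERVL-int went from 5405 ± 274 to 1205 ± 245 (log2 fold change -2.18, SE 0.12, limma adjusted p = 1.8e-13) and its long terminal repeat (LTR) MT2_Mm from 1269 ± 39.6 to 382 ± 63.5 (-1.74, SE 0.13). The largest fall was that of ERVB4_2-LTR_MM (-2.19), and after MERVL-int and MT2_Mm followed RLTR6B_Mm (-1.60) and RLTRETN_Mm (-1.17). RLTR34B_MM rose from 50.2 ± 2.39 to 167 ± 16.8 (1.71, SE 0.19, limma adjusted p = 4.9e-07).

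In all, 46 repeat names rose and 22 fell, 68 of 767, but this split followed the scaling. With the deposited factors, which were set mainly by genes, the median repeat stood at 0.26. With TMM over repeat names, 3 rose and 31 fell, and with median-of-ratios factors over repeat names, 3 rose and 36 fell, so that 67.6% of calls were rises against 8.8% and 7.7%. MERVL-int was at -2.43 and -2.44 under these scalings. The calls of 12 named rises were lost under both. With TMM over repeat names, MER67B was at 1.70 (1.93 with the deposited factors), MLTR13 at 1.70 (1.91), Tigger18a at 1.501 (1.73) and MER77B at 1.19 (1.43), so that these changes stayed large. Smaller ones were MT2A at 0.30, RLTR9E at 0.38, MuRRS4-int at 0.35, RLTR1B at 0.34, MTC at 0.16, ORR1A2 at 0.14, MTD at 0.11 and B1_Mur1 at 0.07. Without KD control replicate 2, the calls of MLTR13 (2.04), Tigger18a (1.24), MER77B (1.01), MT2A (0.55), RLTR9E (0.54), MuRRS4-int (0.64), RLTR1B (0.67), MTC (0.43), ORR1A2 (0.27), MTD (0.29) and B1_Mur1 (0.34) were lost. Without replicate 1 of KD control, those of MER67B (1.55), MLTR13 (1.79), MT2A (0.56), MuRRS4-int (0.56), RLTR1B (0.52), MTC (0.39), ORR1A2 (0.52), MTD (0.44) and B1_Mur1 (0.32) were. MER67B (1.96 and 1.90), MLTR13 (1.65 and 2.18), Tigger18a (1.76 and 1.71) and MER77B (1.45 and 1.40) were also lost without KD Zscan4 replicate 1 and without its replicate 2, and MuRRS4-int (0.57) without the latter. MLTR13 was also lost with a pseudocount of 0.1 (2.19), and B1_Mur1 with library sizes of the gene table (0.33). The count was 27 without KD control replicate 1, 12 without KD control replicate 2 (4 rises and 8 falls), 166 without KD Zscan4 replicate 1 and 66 without KD Zscan4 replicate 2.

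By list, MERVL-int and MT2_Mm fell and MT2A (0.56) rose among 8 MERVL elements, 2 and 2 adjusted over the list alone. The median was 0.16, the mean -0.30 and the test pointed down (camera adjusted p = 0.018, adjusted p = 0.573 with an estimated correlation). Of 19 ETn, MusD and MERVK elements, RLTRETN_Mm, MMETn-int (-0.79), ETnERV-int (-0.70), ERVB7_1-LTR_MM (-0.60) and MMERVK10C-int (-0.60) fell and RLTR9E (0.63) rose, 5 and 1 adjusted over the list alone. Their median was -0.0084 (camera adjusted p = 1.8e-04, adjusted p = 0.561 with an estimated correlation). IAPEY4_I-int (-0.73) fell among 19 IAP elements, as adjusted over the list alone, with a median of 0.17, a mean of -0.04 and a test pointing down (camera adjusted p = 0.026, adjusted p = 0.561 with an estimated correlation). L1Md_Gf (-0.90) and L1Md_T (-0.47) fell among 11 young LINE-1 names, as adjusted over the list alone, with a median of 0.06, a mean of -0.07 and a test pointing down (camera adjusted p = 0.037, adjusted p = 0.606 with an estimated correlation). B1_Mur1 (0.33) rose among 17 SINEs, 3 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0071, adjusted p = 0.573 with an estimated correlation).

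RLTR6B_Mm, RLTR4_Mm (-0.55) and RLTR4_MM-int (-0.41) fell and MuRRS4-int (0.60) and RLTR1B (0.59) rose among 16 gammaretroviral ERV1 elements, 3 and 3 adjusted over the list alone. Their median was 0.11, their mean 0.05, and the test pointed down without passing (limma camera adjusted p = 0.066). ORR1A1 (0.76), MTC (0.41), ORR1A2 (0.40) and MTD (0.36) rose among 19 MaLR elements, 6 with 1 fall adjusted over the list alone, at a median of 0.21 (limma camera adjusted p = 0.156). The calls of MMETn-int (-0.75 and -0.83), ETnERV-int (-0.66 and -0.74), IAPEY4_I-int (-0.73 and -0.74), L1Md_Gf (-0.88 and -0.93), L1Md_T (-0.37 and -0.57) and RLTR4_Mm (-0.60 and -0.49) were lost without KD control replicate 1 and without replicate 2, in that order. That of L1Md_T was also lost without KD Zscan4 replicate 1 (-0.21), and that of ORR1A1 without KD control replicate 1 (0.71). With fry in place of camera no repeat list passed. Satellite repeats were not analysed here.

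The overexpression comparison asked which transcripts moved when Zscan4c was supplied from a plasmid. The summed Zscan4 signal was 375 ± 20.4 in OE control and 5595 ± 401 in OE Zscan4 (n = 2 each), a log2 fold change of 3.90 (SE 0.08). Its unadjusted limma p was 2.1e-20. Zscan4c rose from 67.6 ± 10.7 to 1027 ± 65.8 (3.91, SE 0.13, limma adjusted p = 6.3e-13). All 9 members rose, also adjusted over the list alone, with a median of 3.91 (camera adjusted p = 1.2e-14, adjusted p = 0.129 with an estimated correlation). Zscan4c made up 18.4% of the family signal in OE Zscan4 and 18.0% in OE control. Reads of the introduced coding sequence are counted with those of the endogenous genes, so the share from the plasmid is not known.

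The 2-cell-like list rose. Of 42 measured members, 36 rose and 3 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 2.83 (camera adjusted p = 2.3e-14, adjusted p = 0.129 with an estimated correlation). Gm4340 rose from 31.1 ± 1.80 to 464 ± 53.2 (3.85, SE 0.16, limma adjusted p = 8.9e-12), Gm21304 from 13.4 ± 1.43 to 214 ± 31.4 (3.89), Usp17lc from 11.9 ± 0.65 to 101 ± 30.7 (2.94) and Tcstv3 from 5.36 ± 3.21 to 41.4 ± 0.09 (2.84). Abcb5 had 2 reads against 54, a ratio of 27.2 (7.17 to 230). The 3 that fell were Obox6 (-1.60), P4ha2 (-1.18) and Ddit4l (-0.67). Those that did not pass were Duxf3, Sp140 (0.66) and Trim43c (0.65). Duxf3 was at 4.08 ± 4.42 in OE control and 7.60 ± 2.78 in OE Zscan4 (1.06, limma adjusted p = 0.24), and without OE control replicate 2 it passed at 2.10. Tcstv1 and Zfp352 were not analysed here in this arm.

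Across all genes, 8111 of 18292 passed, with 4072 rises and 4039 falls, of which 588 and 1259 were at least 2-fold. AA623943 had 3 reads against 99, a ratio of 33.2 (11.1 to 164). Outside the Zscan4 family, the next largest rises were Gm21037 from 8.49 ± 2.56 to 205 ± 15.8 (4.46), Gm5039 (4.16) and Gm16478 (3.97).

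The largest falls were Y-linked genes and an X-linked cluster of Xlr genes. Eif2s3y fell from 1052 ± 46.2 to 8.17 ± 7.05 (-7.10, SE 0.35, limma adjusted p = 6.1e-11), with Ddx3y at -6.08 and Uty at -6.02. Uba1y had 148 reads in OE control and 3 in OE Zscan4, a ratio of 0.0204 (0.0042 to 0.0608). Xlr3c (chromosome X, 73254540 to 73265390) fell from 571 ± 20.7 to 7.01 ± 0.61 (-6.16, SE 0.20, limma adjusted p = 8.1e-13). Xlr5b (-4.86), Xlr5c (-4.69), Xlr4b (-4.31) and Xlr5a (-4.19) followed. The metallothionein gene Mt4 had 84 reads against 3, a ratio of 0.0360 (0.0073 to 0.109). All 4 genes of the Y-linked list fell, as adjusted over the list alone, with a median of -6.05 (camera adjusted p = 4.7e-06, adjusted p = 0.149 with an estimated correlation). Their summed signal in OE Zscan4 was 0.98% of that in OE control. Of 8 genes annotated to chromosome Y, 5 fell, and Gapdh-ps15 (0.14), Gm20775 (0.26) and Gm47283 (-0.12) did not pass.

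Pluripotency genes rose. Among naive pluripotency genes, 20 of 30 rose and Dppa3 (-1.72), Tfcp2l1 (-0.41), Socs3 (-0.41) and Stat3 (-0.29) fell, the same counts as adjusted over the list alone. The median was 0.51 (camera adjusted p = 3.4e-07, adjusted p = 0.222 with an estimated correlation), with Dppa2 at 1.55, Nr0b1 at 1.21 and Zfp42 at 1.08. Pou5f1 rose from 20112 ± 898 to 29120 ± 99.98 (0.53, limma adjusted p = 1.3e-05) and Nanog from 13074 ± 212 to 18282 ± 310 (0.48, adjusted p = 1.8e-05). Of 19 formative and primed genes, 14 rose and none fell (15 and none adjusted over the list alone), with a median of 0.62 (camera adjusted p = 1.9e-08, adjusted p = 0.129 with an estimated correlation). Foxd3 rose from 76.2 ± 2.85 to 589 ± 2.86 (2.93), Zic2 from 176 ± 15.6 to 1003 ± 26.6 (2.51) and Otx2 from 265 ± 18.0 to 720 ± 31.6 (1.44). Etv4, Grhl2, Cdh2, Lefty2 and Pou3f1 did not pass, at values between -0.16 and 0.16.

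Primitive endoderm genes fell in 14 of 23 cases and Lrp2 (1.13) and Lamc1 (0.32) rose (15 and 3 adjusted over the list alone). The median was -0.55 (camera adjusted p = 0.0020, adjusted p = 0.231 with an estimated correlation), with Hnf4a at -1.59, Cubn at -1.35 and Srgn at -1.33. Trophectoderm genes fell in 10 of 17 cases and Tfap2a (1.16) and Peg10 (0.76) rose, the same adjusted over the list alone, with a median of -0.63 (camera adjusted p = 0.0040, adjusted p = 0.238 with an estimated correlation). The keratin gene Krt19 fell from 325 ± 27.8 to 47.5 ± 8.55 (-2.76) and Plet1 was at -1.96. In the mesoderm list Id3 (1.89), Msx1 (1.48) and Msx2 (0.76) rose and Mesp1 (-2.52), Tbx6 (-1.31) and Mesp2 (-0.57) fell among 18, the same adjusted over the list alone. The median was -0.06 and the mean -0.15, with a test that pointed up without passing (limma camera adjusted p = 0.992). The Msx1 and Tbx6 calls were lost with DESeq2 (1.725 and -1.38 there) and without single libraries. Msx1 was at 1.44 without OE control replicate 1, at 1.19 without OE Zscan4 replicate 1 and at 1.77 without its replicate 2. Tbx6 was at -1.16 without OE control replicate 2. Of 11 neural ectoderm genes, 7 rose and Map2 (-0.87), Nes (-0.79) and Elavl3 (-0.56) fell, the same adjusted over the list alone, with a median of 0.69 (camera adjusted p = 0.032, adjusted p = 0.229 with an estimated correlation). Gbx2 rose from 283 ± 33.6 to 1225 ± 53.4 (2.11) and Pax6 from 118 ± 23.3 to 389 ± 12.8 (1.72). The list's call was lost with members of at least 1 CPM (limma adjusted p = 0.0777), for a mean of at least 20 (0.0786) and without chromosomes 1, 11 and Y (0.105), in a range over its alternatives from 1.9e-04 to 0.229.

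Of 21 fibroblast and mesenchyme genes, 9 fell and Fbn1 (1.14), Vim (0.52) and Loxl1 (0.48) rose (10 and 3 adjusted over the list alone), at a median of -0.31 (limma camera adjusted p = 0.109). Germline genes fell in 13 of 31 cases and Dmrtb1 (0.94), Stra8 (0.48), Zcwpw1 (0.44) and Tex11 (0.42) rose (15 and 5 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 6.9e-04, adjusted p = 0.169 with an estimated correlation). Gm9 was at -4.07 and Xlr3b fell from 735 ± 19.5 to 88.7 ± 8.45 (-3.04). Repressors of retroelements and heterochromatin rose in 24 of 41 cases and Uhrf2 (-0.50) and Chaf1b (-0.26) fell (25 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 3.4e-07, adjusted p = 0.129 with an estimated correlation). Myc rose from 195 ± 44.3 to 790 ± 19.6 (2.03, SE 0.12, limma adjusted p = 1.4e-09) and Trim28 from 26718 ± 130 to 46651 ± 1519 (0.80, adjusted p = 2.1e-07). Telomere and meiotic recombination genes rose in 9 and fell in 9 of 27 cases, as adjusted over the list alone, with a median of -0.0095 (limma camera adjusted p = 0.588).

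Targets of p53 fell in 15 of 26 cases and Tigar (0.83), Sesn2 (0.55), Bax (0.37) and Perp (0.31) rose, the same adjusted over the list alone. The median was -0.31 (camera adjusted p = 0.0042, adjusted p = 0.239 with an estimated correlation), and the cell cycle inhibitor gene Cdkn1a fell from 1561 ± 30.4 to 611 ± 1.60 (-1.35, SE 0.07, adjusted p = 3.6e-10). Integrated stress response genes rose in 18 of 26 cases and Ddit4 (-1.68) and Ddit3 (-1.25) fell, the same adjusted over the list alone, with a median of 0.32 (camera adjusted p = 2.4e-04, adjusted p = 0.351 with an estimated correlation) and the arginine transporter gene Slc7a3 at 1.29. That list missed the threshold with fry (limma adjusted p = 0.0539, and 1.8e-04 to 0.351 over its alternatives). Interferon response genes fell in 17 of 24 cases and Ddx58 (0.69) rose (17 and 2 adjusted over the list alone). Their median was -0.67 (camera adjusted p = 5.3e-05, adjusted p = 0.149 with an estimated correlation), with Ifi27 at -2.85, Oas1b at -2.16 and the peptide transporter gene Tap1 at -2.03.

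Genes of sterol synthesis and glycolysis fell and mitochondrially encoded genes rose. Cholesterol synthesis genes fell in 21 of 24 cases and none rose (21 and 1 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 2.9e-09, adjusted p = 0.222 with an estimated correlation). Insig1 fell from 2291 ± 53.7 to 1221 ± 7.20 (-0.91), and Ebp and Idi1 were among those that did not pass. Of 33 measured identifiers of glycolysis and hypoxia genes, of which Aldoa has 2, 21 fell and Kdm3a (0.51) and Pgam1 (0.25) rose (22 and 2 adjusted over the list alone). The median was -0.50 (camera adjusted p = 7.7e-09, adjusted p = 0.222 with an estimated correlation), and the aldolase gene Aldoc fell from 1970.4 ± 48.0 to 341 ± 16.1 (-2.53, SE 0.08, adjusted p = 6.3e-13), with Ndrg1 at -1.90 and Bnip3 at -1.43. Mitochondrially encoded genes rose in 9 of 13 cases, as adjusted over the list alone, with a median of 0.43 (camera adjusted p = 6.8e-05, adjusted p = 0.222 with an estimated correlation). mt-Nd1 was at 0.97 and mt-Cytb at 0.96, and mt-Co1, mt-Co3, mt-Nd5 and mt-Nd6 did not pass. Among 50 replication-dependent histone genes, 8 fell and Hist1h4i (0.79) and Hist1h2bc (0.42) rose (7 and 1 adjusted over the list alone), at a median of -0.13 (limma camera adjusted p = 0.316). Of 36 imprinted genes, 16 rose and 8 fell (17 and 8 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.036, adjusted p = 0.222 with an estimated correlation). Nnat was at -1.28. That call was lost with members of at least 1 CPM (limma adjusted p = 0.0983), for a mean of at least 20 (0.0924) and without chromosomes 1, 11 and Y (0.0653), in a range over its alternatives from 0.0063 to 0.222.

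**Figure D3:**
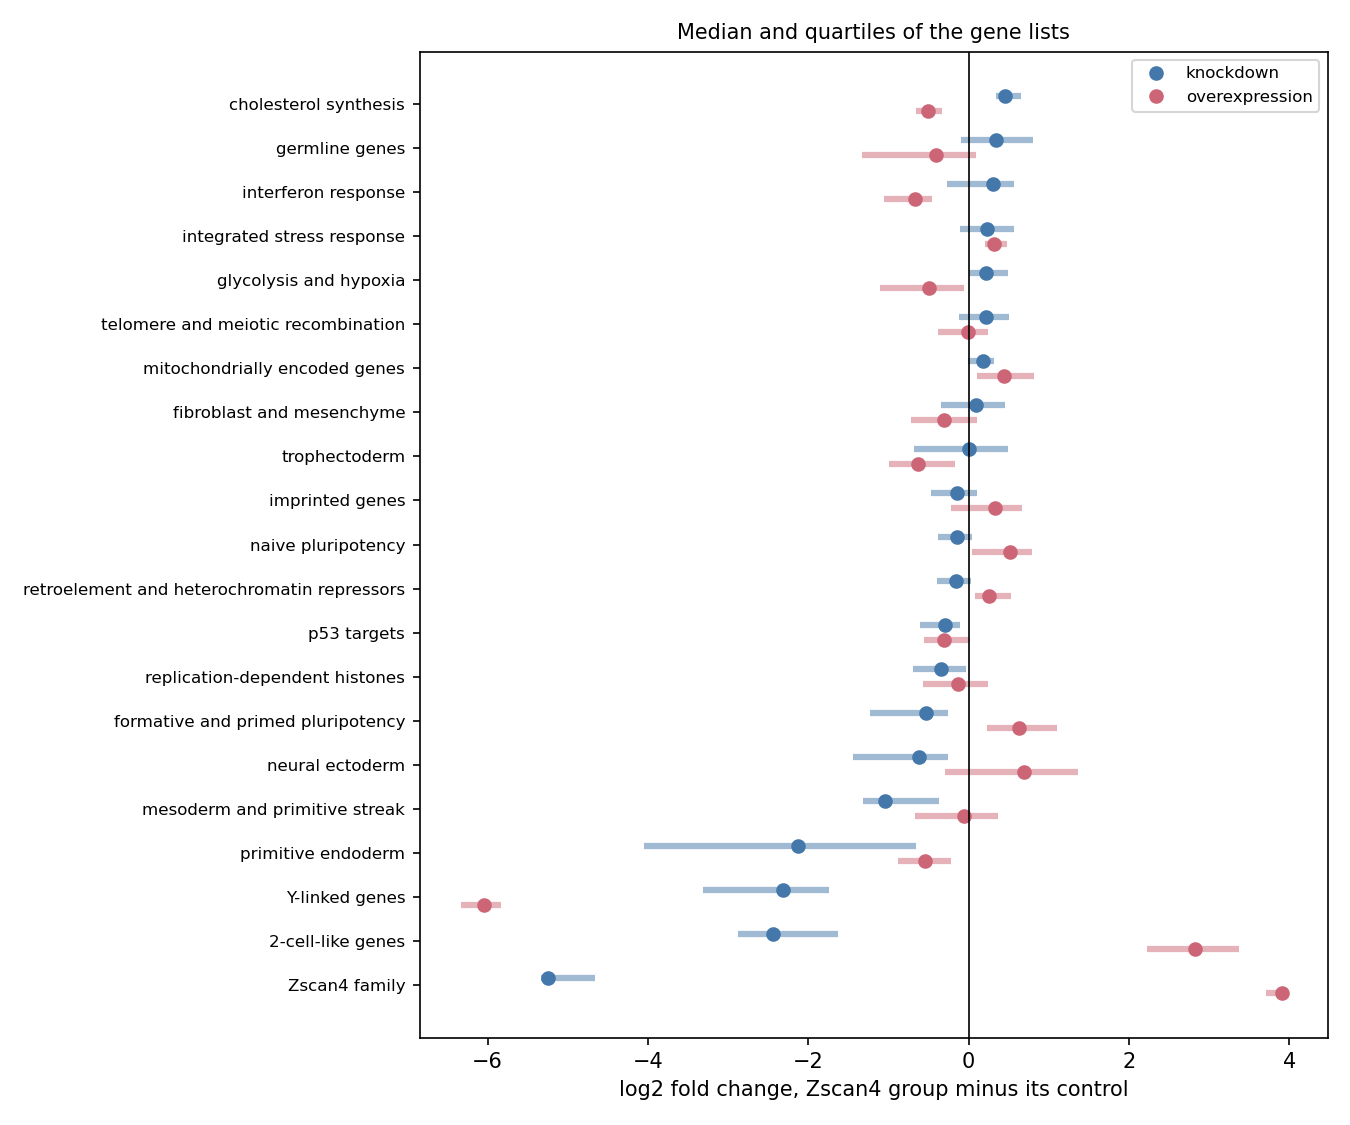
Median (points) and quartiles (bars) of the log2 fold changes of the measured members of 21 gene lists in the knockdown and the overexpression, each Zscan4 group minus its own control. The Zscan4 family stood at -5.25 and 3.91, and the 2-cell-like genes at -2.44 and 2.83.

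Genes of chromosome 11 were lower in OE Zscan4. The median of its 1087 protein-coding genes with a mean of at least 20 was -0.34 (quartiles -0.68 and -0.08), a fold of 0.79, and the medians of the other 18 autosomes lay between -0.07 and 0.09. Within chromosome 1, however, 3 of 20 windows of 10 Mb, which are adjacent, had medians of -0.29, -0.36 and -0.38. Windows of other chromosomes than 1 and 11 were not analysed here. Chromosome 11 held 837 of the 8111 called genes, with 104 rises and 733 falls. Without chromosomes 1, 11 and Y, 6742 genes were called.

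MERVL also rose with Zscan4c. MERVL-int went from 848 ± 62.1 to 7559 ± 429 (3.16, SE 0.21, limma adjusted p = 6.8e-46). MT2_Mm went from 323 ± 29.0 to 1764 ± 9.64 (2.45, SE 0.21, limma adjusted p = 4.3e-27). For repeats of this arm limma drew the variance from the trend over all repeats, with infinite prior degrees of freedom. The p-values of these repeats therefore leave out each repeat's own spread. ERVB4_2-LTR_MM rose from 3.42 ± 1.94 to 39.7 ± 3.52 (3.27), RLTR6B_Mm from 62.1 ± 7.91 to 247 ± 5.73 (1.98), and the young LINE-1 L1Md_A from 994 ± 174 to 4104 ± 44.5 (2.06, SE 0.21, limma adjusted p = 4.2e-20). IAPEy-int fell from 230 ± 36.3 to 24.3 ± 2.78 (-3.18, SE 0.27, limma adjusted p = 2.1e-28), LTR53 from 77.1 ± 14.2 to 17.4 ± 0.57 (-2.07) and IAPEY_LTR from 89.1 ± 1.29 to 27.4 ± 0.32 (-1.66). RLTR34B_MM (-1.37) and RLTR27 (-1.19) completed the 5 largest falls. Values are summed by repeat name, so how much of these falls came from chromosome Y, where genes also fell, cannot be told.

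In all, 32 of 834 repeat names passed, 21 rising and 11 falling, and 107 had an unadjusted p under 0.05. This count depended on which library was left out. It was 189 without OE control replicate 1, 188 without its replicate 2, and 8 without either OE Zscan4 library. The split also moved, with 44 rises and 145 falls without OE control replicate 1 and 165 rises and 23 falls without its replicate 2. TMM over repeat names gave 103 calls and median-of-ratios factors over repeat names 100. Without OE Zscan4 replicate 1 and without its replicate 2, in that order, the calls of RLTR34B_MM (-1.49 and -1.245), RLTR27 (-1.31 and -1.06), L1Md_Gf (1.55 and 1.62), L1Md_T (1.39 and 1.45), L1Md_F3 (1.04 and 1.00), MMERVK10C-int (-0.9998 and -0.73), ERVB7_1-LTR_MM (0.75 and 0.69), RLTR1B-int (-0.82 and -0.95) and ORR1A3-int (0.73 and 0.81) were lost. Those of ERVB7_1-LTR_MM (0.71) and ORR1A3-int (0.76) were also lost with library sizes of the gene table.

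By list, MERVL-int and MT2_Mm rose among 8 MERVL elements, as adjusted over the list alone, with a median of 0.24 (camera adjusted p = 6.6e-09, adjusted p = 0.507 with an estimated correlation). L1Md_A, L1Md_Gf (1.58), L1Md_T (1.42), L1Md_F3 (1.02) and L1Md_F (0.82) rose among 11 young LINE-1 names, 8 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 7.8e-13, adjusted p = 0.507 with an estimated correlation). IAPEY_LTR fell among 18 IAP elements (2 with 1 rise adjusted over the list alone), at a median of -0.12 (limma camera adjusted p = 0.268). RLTR6B_Mm rose and RLTR1B-int (-0.89) fell among 16 gammaretroviral ERV1 elements (2 and 1 adjusted over the list alone), at a median of 0.25 (limma camera adjusted p = 0.268). ERVB7_1-LTR_MM (0.72) rose and MMERVK10C-int (-0.87) fell among 19 ETn, MusD and MERVK elements (5 and 1 adjusted over the list alone), at a median of 0.07 (limma camera adjusted p = 0.277). ORR1A3-int (0.77) rose among 19 MaLR elements, as adjusted over the list alone, at a median of 0.11 (limma camera adjusted p = 0.277). With fry neither the MERVL nor the LINE-1 list passed. None of 17 SINEs passed in limma, nor had any an unadjusted p under 0.05 (0 of 17), and the median was -0.0081 (camera adjusted p = 0.931).

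Genes called in both comparisons moved in opposite directions more often than independent lists would. Of the 17409 genes in both tables, 1158 fell in the knockdown and rose in the overexpression, against 746 for independent lists (Fisher's exact test, two-sided, p = 2.7e-75), and 986 rose in the knockdown and fell in the overexpression, against 673 (p = 8.8e-48). Together these 2144 were 62.2% of the 3446 genes called in both. By Fisher's exact test 676 rose in both, against 709 (p = 0.12), and 626 fell in both, against 707 (p = 1.1e-04). Across genes, which are not independent replicates, the fold changes of the comparisons had a Pearson correlation of -0.23 and a Spearman correlation of -0.14. Fisher's exact test likewise takes genes as independent, so its p-values do not measure the spread between libraries or clones. The comparisons share no control library. With calls from DESeq2, 1235 genes moved oppositely and 730 together.

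The opposite genes with the largest changes were Zscan4-ps3 (-5.67 in the knockdown and 4.59 in the overexpression), Zscan4c, Zscan4-ps1 (-5.18 and 4.11), Zscan4f (-5.27 and 3.86) and BC147527, which had 46 reads against 1 in the knockdown (ratio 0.0217, 95% counting interval 0.00054 to 0.127) and 1 against 51 in the overexpression (51.4, 8.81 to 2068). The same-direction genes with the largest changes were the Y-linked Ddx3y, Uty (-2.43 and -6.02) and Uba1y (-2.20 in the knockdown), Mzb1, with 29 reads against 2 in the knockdown (ratio 0.0687, 0.0079 to 0.272) and -2.75 in the overexpression, and Tpbgl, with 44 reads against 2 (0.0453, 0.0053 to 0.174) and -2.03. Among 763 repeat names in both tables, 11 fell in the knockdown and rose in the overexpression, against 0.61 for independent lists (Fisher's exact test, two-sided, p = 1.8e-13). MERVL-int, MT2_Mm, ERVB4_2-LTR_MM, RLTR6B_Mm, L1Md_Gf and L1Md_T were among these. The test counts related names, such as MERVL-int and its LTR MT2_Mm, as independent, which they are not. RLTR34B_MM rose in the knockdown and fell in the overexpression.

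The difference of the 2 effects, knockdown minus overexpression, passed for 7787 of 17409 genes in limma, 3799 higher and 3988 lower. It was -9.25 for Zscan4c (SE 0.23, limma adjusted p = 1.1e-13), -6.78 for Gm4340 (SE 0.25, adjusted p = 1.2e-11), -3.74 for Myc (SE 0.16, adjusted p = 3.8e-11), 7.26 for Rian (SE 0.24, adjusted p = 4.5e-12) and -4.48 for Cubn (adjusted p = 6.0e-07). Trim28 differed by -1.01 and Pou5f1 by -0.66, while Nanog did not pass (-0.13, limma adjusted p = 0.158). By list, 33 of 34 2-cell-like genes were lower and P4ha2 was higher, with a median of -5.29. All 19 formative and primed genes were lower (median -1.26), 28 of 41 repressors lower and 2 higher (-0.47), 21 of 24 cholesterol synthesis genes higher and 1 lower (1.04), 22 of 32 glycolysis and hypoxia genes higher and 4 lower (0.80), and 13 of 22 interferon response genes higher and 2 lower (0.72). For p53 targets 8 were higher and 12 lower of 26 (-0.26), and for the integrated stress response 7 and 7 of 26 (-0.10). The difference of the effects contains that of the controls. On a joint scale, medians of OE control minus KD control were -1.36 in formative and primed genes and -0.42 in repressors. They were 1.06 in cholesterol synthesis, 0.53 in glycolysis and hypoxia, 0.71 in interferon response and -2.26 in 2-cell-like genes. List values above can therefore reflect how the controls differed.

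Both controls were labelled wild type but had received different vectors and drugs, and they differed from each other as a background to these comparisons. Recovered reads of the shared genes were scaled jointly for this, because the tables had been normalised separately. OE control and KD control differed in 10662 of 17409 genes in limma, 5429 higher in OE control and 5233 lower. The Zscan4 family sum was 3563 ± 303 in KD control and 376 ± 21.4 in OE control on this scale, a log2 difference of -3.24 (SE 0.12), with 117 ± 27.8 in KD Zscan4 and 5619 ± 385 in OE Zscan4. Of 34 2-cell-like genes, 31 were lower in OE control, with a median of -2.26. Over the 14751 genes compared, rank correlations were 0.943 to 0.946 between the controls and 0.984 to 0.988 between KD Zscan4 and OE Zscan4. They were 0.976 to 0.977 between KD Zscan4 and its control, and 0.970 to 0.973 between OE Zscan4 and its control.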

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

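Tests chosen only after seeing the data were edgeR on recovered reads, TMM scaling of genes, TMM over repeat names, a mean of at least 20, and chromosomes 1, 11 and Y left out. No fold change named by rule that passed changed direction under any alternative run. No gene list passed under an alternative in a direction other than that of its main test. Directions of lists that missed the threshold were not compared. The balance of rises and falls among called repeats did change. The Zscan4 family sums and MERVL-int passed under every alternative run for them. Without each library in turn the sum lay between -5.17 and -4.69 in the knockdown and between 3.82 and 3.97 in the overexpression, and MERVL-int between -2.39 and -1.97 and between 3.08 and 3.23. In these fits the lone library of a group is assumed to vary like the other group's.

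Gene counts moved with the threshold and the test. In the knockdown, 1387 genes passed with an absolute log2 fold change of at least 1, 4135 at a false discovery rate under 0.01 and 4137 with DESeq2, and in the overexpression 1847 with a log2 fold change of at least 1. In the overlap, 1235 opposite and 730 same-direction genes were counted with DESeq2, and 319 and 71 with a log2 fold change of at least 1. A stricter threshold leaves fewer genes by construction, and for DESeq2 the cause was not tested. edgeR called 6458 and 8046 genes, of which 6253 and 7787 were shared with limma. Leaving out 1 library gave 4415 to 6087 genes in the knockdown and 5965 to 7975 in the overexpression.

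The 2-cell-like list had an adjusted p of 0.1952 in the knockdown and 0.1292 in the overexpression with an estimated correlation in limma's camera, and passed under its other alternatives. Every list that passed with the preset correlation missed the threshold with the estimated one. In simulated data that setting also missed a list with 15 of 30 members raised, so its misses alone do not show unchanged lists. Genes were drawn independently there, so the preset correlation of 0.01 was not tested against correlated genes. Estimated correlations of gene lists in the knockdown ran from -0.049 (mesoderm and primitive streak) to 0.732 (mitochondrially encoded genes). Fry, another set test, found the changed list in simulated data except among overexpression genes (fry adjusted p = 0.0935). It also called 1 of 20 unchanged lists in each knockdown simulation. With fry in place of camera, none of the 7 repeat list calls passed. Of the gene lists 5 calls were lost, which were telomere and recombination genes, glycolysis and hypoxia, mitochondrially encoded genes and histones in the knockdown and the integrated stress response in the overexpression, and 3 were gained, which were interferon response and trophectoderm genes in the knockdown and fibroblast genes in the overexpression.

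Repeat counts were the least stable. In the knockdown, 15 passed with a log2 fold change of at least 1, 19 at a false discovery rate under 0.01, 34 with TMM over repeat names and 39 with DESeq2 size factors over repeat names, and in the overexpression 20, 22, 103 and 100. The counts were 64 and 24 with library sizes of the gene table. Without 1 library the count was 12 to 166 in the knockdown (27 without KD control replicate 1, 12 without KD control replicate 2, 166 without KD Zscan4 replicate 1, 66 without KD Zscan4 replicate 2). In the overexpression it was 8 to 189 (189 and 188 without OE control replicate 1 and 2, 8 without either OE Zscan4 library). Rises and falls went from 46 and 22 to 3 and 31 in the knockdown with TMM over repeat names and to 4 and 8 without KD control replicate 2. In the overexpression they went from 21 and 11 to 44 and 145 without OE control replicate 1. The cause was not tested.

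The labels number the replicates without saying what a number shares, and same-numbered samples did not deviate together (correlations of -0.059, -0.039, -0.098 and -0.029). With a replicate block 40 repeats passed in the knockdown, and no other count moved by over 1.5 times (6924 and 8188 genes, 26 repeats in the overexpression). Of named results 11 lost their call, with the folds as before: the histone list in the knockdown (limma adjusted p = 0.0853, and 0.0041 to 0.517 over its alternatives), MLTR13, MER77B, MuRRS4-int, RLTR1B, L1Md_T, MTC, ORR1A2, MTD and B1_Mur1 in the knockdown, and ERVB7_1-LTR_MM in the overexpression.

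DESeq2 size factors equal the deposited gene factors, so that alternative changed nothing for genes within an arm. A low-value filter of a mean of 1, or none, left out no entry. DESeq2 and limma-voom were not run on repeats, which had no count test.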

Other observations

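Of the tests below, those on chromosome 1 and the Zscan4 level, on Y-linked genes and on leaving out chromosomes 1, 11 and Y were chosen only after the result was seen. Intervals below come from 1000 resamples of genes with the libraries held fixed. They do not measure the spread between libraries or clones.

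On the joint scale, noncoding RNAs of the Dlk1-Dio3 region were lowest in KD control and highest in KD Zscan4. Rian was at 4.40 in KD control, 1749 in KD Zscan4, 127 in OE control and 276 in OE Zscan4, and Meg3 at 1.13, 692, 51.1 and 84.7, and Mirg, with few reads outside KD Zscan4, at 0.90, 93.5, 4.06 and 13.3. Rian was higher in OE control than in KD control by 4.59 (limma adjusted p = 9.4e-12). Dlk1, the protein-coding gene of the region, was at 105, 134, 31.9 and 50.5. Xlr genes on chromosome X had another order, with Xlr3a at 2.03, 128, 1674 and 647 and Xlr3c at 6.76, 4.95, 574 and 7.04. Gata6, a primitive endoderm regulator, was at 428, 20.9, 50.5 and 25.3.

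The controls differed along the gene lists too. Beside the Zscan4 family and 2-cell-like genes, OE control had 17 of 23 primitive endoderm genes lower than KD control (2 higher, median -1.74), 18 of 19 formative genes lower (-1.36), 20 of 24 cholesterol synthesis genes higher (2 lower, 1.06), 22 of 27 germline genes higher (2 lower, 1.24) and 21 of 32 glycolysis genes higher (4 lower, 0.53).

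The first pattern weighed was the shift of chromosome 1 in the knockdown and of chromosome 11 in the overexpression. Medians of 10 Mb windows were above 0.3 in 100% of chromosome 1 windows and below -0.15 in 92.31% of chromosome 11 windows, which is consistent with a copy more of chromosome 1 in KD Zscan4 than in KD control and a copy fewer of chromosome 11 in some or all OE Zscan4 cells than in OE control. In the overexpression 3 of 20 windows of chromosome 1 were also below -0.15, down to -0.38, so such a shift was not confined to chromosome 11, and its cause is open. For chromosome 1 in the knockdown, matched genes of other autosomes argue against a bias with expression or length (difference 0.5855, 95% interval 0.5615 to 0.6079), which was not tested for chromosome 11. For chromosome 1, OE Zscan4 lay above KD control by 0.6345 (0.5956 to 0.6748) relative to other autosomes, although both had a high Zscan4 sum. This argues against the Zscan4 level alone setting chromosome 1 in all 4 groups. These 2 groups also differ in vector and drug, so a Zscan4 effect added to such a difference cannot be told from none. OE control lay above KD control as well, by 0.67 relative to other autosomes. KD control may be the group apart for chromosome 1, and OE control for chromosome 11, whose genes were higher there than in KD control by 0.30. DNA was not measured.

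The second pattern was the low Y-linked expression. In OE Zscan4 the list kept 0.9824% of its control level, which is consistent with loss of the Y chromosome or of a part that holds these genes. Of 8 genes annotated to it 3 did not pass, and whether their reads come from elsewhere was not tested. In KD Zscan4 loss of the whole chromosome is argued against by Eif2s3y, which kept 77.48%. Reads of its X-linked copy are no source of this, as it kept 0.7764% in OE Zscan4. Between the comparisons, 5 Y-linked genes fell in both and 0 went opposite ways, so they did not follow the Zscan4 level across both arms. If OE Zscan4 cells lost these genes, they had to fall there whatever Zscan4 does. This test therefore cannot decide on an effect of Zscan4 in the knockdown. In KD Zscan4, Eif2s3y, at 1010543, lies between Uba1y (818649, 19.6% kept) and Uty (1096861, 18.1% kept). Loss of a single stretch covering Uba1y and Uty would not spare Eif2s3y, so this order argues against it. Shares from 1.56% for Ddx3y to 77.48% for Eif2s3y argue against loss of the whole chromosome in only some cells. Other forms of partial loss in KD Zscan4 stay open and may differ between cells.

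The third pattern was the excess of genes called in opposite directions. It was tested in the 2108 of them left without 36 Zscan4 family and 2-cell-like genes. Between the Zscan4 groups their median absolute log2 difference was 0.192 (0.1818 to 0.2028) of that between the controls, against 0.478 over all genes and 0.796 in genes called in the same direction. Controls lying on either side of a level that both Zscan4 groups share may account for this, although choosing genes by opposite calls itself favours a low ratio. The difference of OE Zscan4 to KD control was 2.377 times (2.232 to 2.538) that between the Zscan4 groups (2.35 with the 36 included). This argues against the Zscan4 level alone setting most of these 2108 genes in all 4 groups. That ratio is not particular to them, at 2.69 in same-direction genes and 1.64 over all genes. It was 0.152 in the 36 genes left out. OE Zscan4 and KD control also differ in vector and drug, so this ratio cannot tell a Zscan4 effect added to such a difference from none. Without chromosomes 1, 11 and Y, genes called in opposite directions were 1.545 times as many as independent lists would share. Over all genes that ratio was 1.55 for falls in the knockdown with rises in the overexpression and 1.47 for the reverse. Leaving out the genes of these chromosomes therefore did not remove the excess. Clone, vector, drug and batch remain open for the controls, and library similarities had been seen before this was tested.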
